A study of Mus musculus with 60 samples.

How the data were processed

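Single fibres were freed from soleus and EDL muscles with collagenase, and RNA of each fibre was amplified over 18 cycles, labelled with Cy3 and hybridised to an Agilent mouse 8x60K array, per the labels' protocols. The arrays were read with Agilent Feature Extraction 10.7.3.1, per the submitters' processing notes. The authors deposited an intensity for each probe and array, on a linear scale. Its background correction and normalization are not given in the sources used here. The values themselves show that the highest is 125263 on all 60 arrays and that values of the same rank differ little between arrays, as after quantile normalization. The lowest listed value differs between arrays, from 4.27 to 55.1, and cells without a listed value were taken as missing, not as 0. Each array listed 27.5% to 56.4% of the probes. Precision is set by the number of arrays, and a probe that an array does not list has no level there.

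The 140 control features were left out of the tests. The deposited intensity was put on the log2 scale and normalized between arrays by rank from the brightest probe down, which moved a value by at most 0.378 log2 units and by a median of 0.0157. A probe was tested when at least 5 arrays of every type listed it and at least 10 arrays had it above the median of all probes, which left 17235 probes. Among these, 6.70% of the cells were missing. Where cells are missing because they are dim, the mean of a type is too high. Of 69252 missing cells of tested probes, 41913 (60.5%) had all other listed values of that type above the lowest value of the array, 21984 (31.7%) had them all above 2 times that value, and 253 (0.365%) had them all above a log2 intensity of 10. Few missing cells thus lie where all other listed values of the type are bright. The missing cells are not shown to be dim, and the direction of any bias stays open. Of the 16251 probes whose identifier starts with A_30, 27 were tested.

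Groups and replicate numbers follow the labels, which also give the muscle and the animal of each fibre. Several fibres came from the same animal. The main test was a linear model over all 60 arrays with a mean per type and the animal as a random block, with a consensus correlation of 0.170 from duplicateCorrelation, followed by limma's moderated variances with a trend and robust estimation (limma 3.58.1 in R 4.3.3). Because limma's contrasts only approximate the standard errors where cells are missing, each probe was fitted by generalised least squares with its own missing cells. On probes without missing cells the coefficients equalled those of lmFit to within 1.42e-14. All tests are two-sided and adjusted by Benjamini-Hochberg over the probes tested, with a threshold of 0.05. Each log2 fold change is given ± its standard error, and each level ± the SD over the listed arrays.

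The design fixed before the data were examined named genes: the MyHC genes in every sample, the 10 (or 5) genes with the largest changes in each direction per comparison, 4 members of each of the fixed gene lists, and the 10 genes of largest F. None of the probe identifiers matched the RefSeq table given, and the files do not pair probes with genes. The probe was therefore the unit, at most 2 probes per direction are named in a comparison (those of largest change that passed the test, and the leading 2 of the F test), and the gene lists, the cell type markers, the tests of gene sets with their alternatives and the summary of several probes of a gene were not run. Any other probe named was chosen after its values were seen.

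The test was tried on simulated data with the real means, spreads, missing cells and animals, 50 probes being changed by each of 4 fold sizes. For MyHC-2A minus MyHC-1 it called 82.0% of 4-fold and 46.0% of 2-fold changes, and 4.88% of its calls were unchanged probes. For Hyb-2X/2B minus MyHC-2X the same shares were 84.0%, 26.0% and 6.25%. Alternatives were other scalings, filters, thresholds, array weights, other treatments of the animal, the replicate number as a block in place of the animal, only the compared types in the fit, and each array left out in turn. Alternatives added after seeing the data were the values without rank normalization, a common floor, covariates, and fits without arrays that stood apart. The slide of each array is not given in the sources used here and was not tested. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.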

Results

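Transcript levels were measured in 60 single muscle fibres from the hindlimbs of male CD1 mice aged 3 months, with 10 fibres for each of 6 fibre types. The type of a fibre was set by its myosin heavy chain (MyHC) protein, the motor protein whose isoforms separate slow fibres (MyHC-1) from fast ones (MyHC-2A, MyHC-2X and MyHC-2B). Hybrid fibres held 2 isoforms, written Hyb-2A/2X and Hyb-2X/2B. Per the labels, a piece of each fibre was typed on a protein gel and the rest gave the RNA, so the type and the transcripts come from the same cell. The 40 fibres of types MyHC-1, MyHC-2A, Hyb-2A/2X and MyHC-2X came from the soleus, a slow postural muscle, of 13 animals. The 20 fibres of types Hyb-2X/2B and MyHC-2B came from the extensor digitorum longus (EDL), a fast muscle, of 10 animals. Each type drew on 6 to 9 animals. The deposited table listed an intensity for 15324 to 31426 of the 55681 probes on each array, and the number of arrays, not a count depth, limits the precision. The files do not pair probes with genes, so results are given per probe, with few identifiers, and the levels of the MyHC genes themselves are not analysed here.

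The soleus types and the EDL types separated with some overlap, a split in which muscle, type and animals cannot be told apart. The second principal component, with 11.3% of the variance, had a mean score of 34.1 ± 9.18 (SD, n = 10) in MyHC-2B and 25.2 ± 15.9 in Hyb-2X/2B, against -20.9 ± 6.81 in MyHC-1, -14.6 ± 7.03 in MyHC-2A, -9.39 ± 10.8 in Hyb-2A/2X and -14.5 ± 13.4 in MyHC-2X, so the soleus types overlap on it. Of 17235 probes tested, 2058 (11.9%) differed among the 6 types at an adjusted p under 0.05 in the moderated F test. Probe A_55_P2052330 was the clearest by adjusted p (1.24e-25), with a mean log2 intensity of 13.61 ± 0.38 (SD, n = 10) in MyHC-1 and 7.80 ± 0.93 in MyHC-2B. Probe A_55_P2032258 had a mean of 13.94 ± 0.31 in MyHC-1 and 8.40 ± 0.58 (n = 8 arrays with a listed value) in MyHC-2B. The first component held 24.5% of the variance and split types: 10 arrays (5 Hyb-2A/2X, 2 MyHC-2A, 2 MyHC-2X and 1 Hyb-2X/2B) had scores of at most -58.2, and the other 50, all MyHC-1 and MyHC-2B arrays among them, lay at -34.4 or above.

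**Figure D1:**
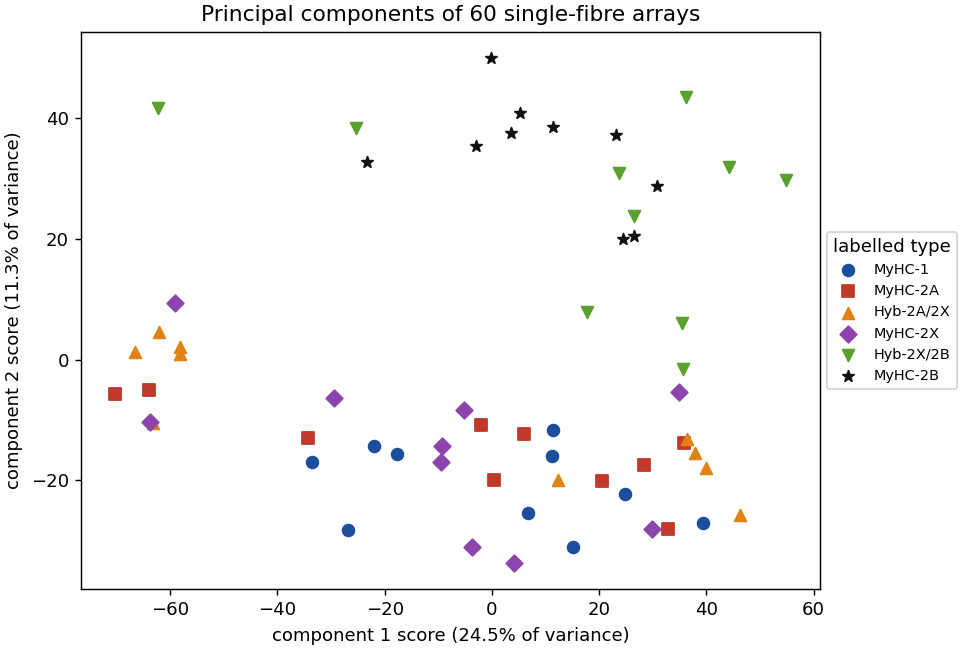
Scores of the 60 arrays on the first (x axis) and second (y axis) principal components of log2 intensity, with a marker per labelled fibre type. MyHC-2B arrays lie at 19.9 or above on the second component, Hyb-2X/2B arrays reach down to -1.58 and soleus arrays up to 9.43, and 10 arrays lie apart at the left on the first, at -58.2 or below.

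Arrays labelled MyHC-2A were set against MyHC-1 to compare fast oxidative with slow fibres of the same muscle. MyHC-2A fibres had 236 probes higher and 76 lower than MyHC-1, and 24 of these differed by 8-fold or more. Probe A_51_P431785 was higher by 7.29 ± 0.48 log2 units (SE, adjusted p = 1.41e-16) and was bright on all fast types, with a mean log2 intensity of 12.92 ± 1.22 (SD, n = 10) in MyHC-2A and 5.48 ± 2.00 on the 6 MyHC-1 arrays that listed it, a dim level that leaves the size of the change uncertain. Probe A_55_P2088375 was higher by 7.45 ± 0.62 (adjusted p = 4.52e-13). Probe A_55_P2093232 fell by 6.47 ± 0.95 (adjusted p = 5.39e-06) and A_55_P2090205 fell by 5.27 ± 0.74 (adjusted p = 1.95e-06). On the array labelled MyHC-2A replicate 3 these last probes were at the MyHC-1 level, with A_55_P2093232 at 15.31 against 15.34 ± 0.25 in MyHC-1. On replicate 9, at 14.67 and 14.61, they were below every MyHC-1 array but above the other 8 MyHC-2A arrays. Without these 2 arrays and MyHC-2X replicates 6 and 8, all picked by their values, A_55_P2093232 fell by 7.95 ± 0.54 and A_55_P2090205 fell by 6.41 ± 0.33. The moderated test called 312 probes in all. With the animal as a fixed block the count was 85, without the 8 arrays that list the dimmest values it was 119 (78 higher and 41 lower), and without the 10 arrays apart on the first component it was 160.

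**Figure D2:**
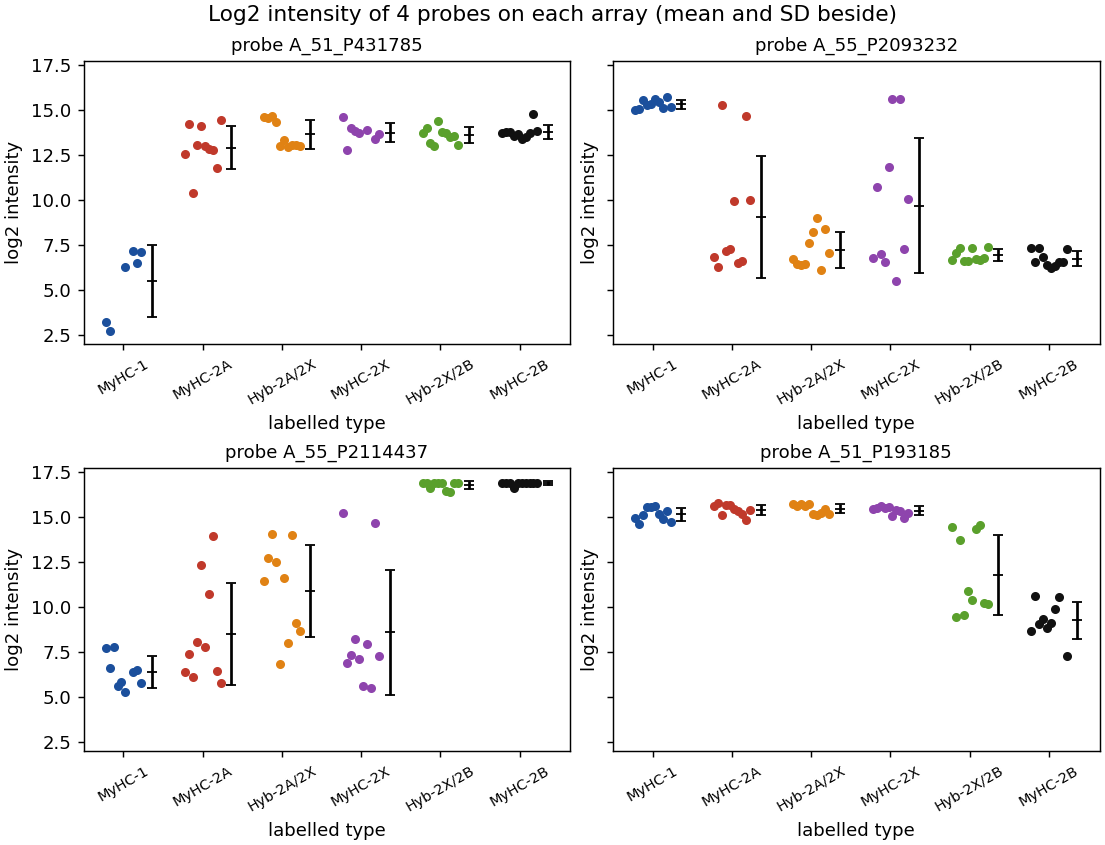
Log2 intensity (y axis) of 4 probes on each array that listed them, by labelled type (x axis), with the mean and SD beside each group of points. A_55_P2093232 lies at 15.01 or above on all MyHC-1 arrays and at 14.67 or above on 4 arrays labelled MyHC-2A or MyHC-2X, and A_51_P193185 spreads from 9.42 to 14.60 in Hyb-2X/2B.

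Arrays labelled MyHC-2X showed the same kind of contrast with MyHC-1. They had 164 probes higher and 48 lower, of which 19 differed by 8-fold or more. Probe A_51_P431785 was higher by 8.32 ± 0.51 log2 units (adjusted p = 6.03e-18), a size that its dim level in MyHC-1 again leaves uncertain. A_55_P2088375 was higher by 6.86 ± 0.64 (adjusted p = 2.50e-11), while A_55_P2093232 fell by 5.56 ± 0.93 (adjusted p = 1.13e-04) and A_52_P657360 fell by 4.81 ± 0.93 (adjusted p = 1.40e-03). The arrays labelled MyHC-2X replicates 6 and 8 carried A_55_P2093232 at 15.64 and 15.62 and did not list A_51_P431785, unlike the other 8 arrays of that label. Without these 2 arrays and MyHC-2A replicates 3 and 9, A_55_P2093232 fell by 7.24 ± 0.55 and A_52_P657360 fell by 6.42 ± 0.71, and A_55_P2088375 was higher by 7.89 ± 0.33. The moderated test called 212 probes. This count was 483 without these 2 arrays, which were picked by their values, and 44 with the animal as a fixed block, and leaving out a single array gave 91 to 338, the lowest without MyHC-2X replicate 1 and the highest without MyHC-2X replicate 6. Leaving out MyHC-1 replicate 1, MyHC-1 replicate 2 or MyHC-2X replicate 9 gave 134, 138 and 122, and the count was 62 with only these 2 types in the fit, 113 with fibres of an animal averaged, 61 without the 10 arrays apart on the first component and 60 (29 higher and 31 lower) without the 8 arrays of dimmest listed values.

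Of the probes called in both contrasts with MyHC-1, 133 were higher and 31 lower in both MyHC-2A and MyHC-2X, and 0 went in opposite directions. Independent lists of these sizes would share 2.25 and 0.212. Log2 fold changes of the 2 contrasts correlated across probes at r = 0.795, against 0.456 in simulated unchanged groups that share the MyHC-1 arrays, and their covariance was 0.171 against a simulated 0.0632. With MyHC-1 split into replicates 1 to 5 and 6 to 10, so that each contrast had its own reference arrays, r was 0.266 or 0.358 and 27 or 44 probes were called in the same direction in both. MyHC-1 replicates 5 and 6 came from the same animal, so the 2 references are not fully separate. Probes are not independent replicates, and these values describe the arrays only.

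**Figure D3:**
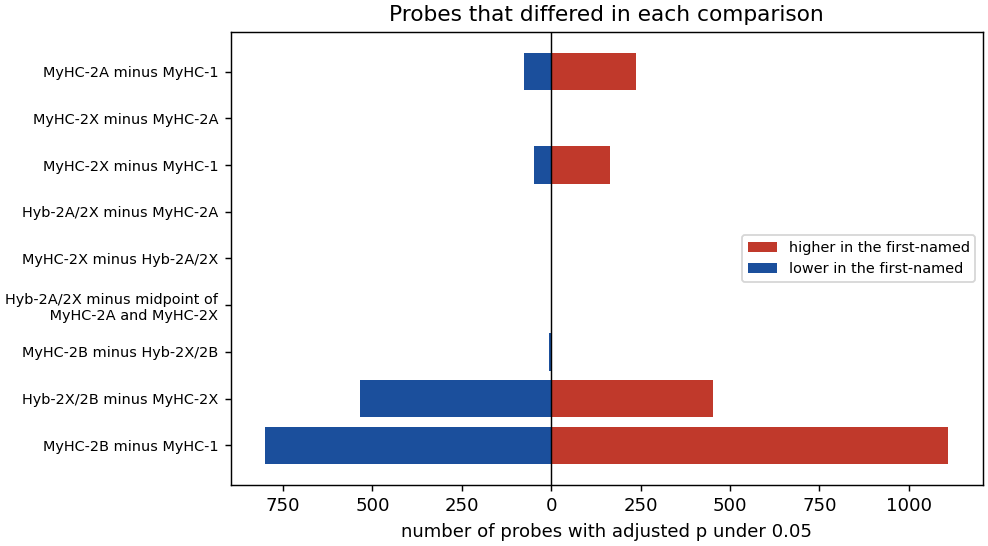
Number of probes (x axis) with an adjusted p under 0.05 in each comparison (y axis), higher to the right and lower to the left in the first-named type. The 4 comparisons among MyHC-2A, Hyb-2A/2X and MyHC-2X have 0 calls, and MyHC-2B minus MyHC-1 has 1111 higher and 800 lower.

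The 3 fast soleus types were not told apart. No probe passed the test between MyHC-2X and MyHC-2A, between Hyb-2A/2X and MyHC-2A, or between MyHC-2X and Hyb-2A/2X. Hyb-2A/2X also did not depart from the midpoint of the pure types at any probe. At an unadjusted p under 0.05 the moderated test gave 315, 440, 594 and 617 probes in this order, or 1.83% to 3.58% of those tested. Unchanged probes in simulated data gave more, 5.11% for MyHC-2X minus MyHC-2A and 4.99% for Hyb-2A/2X minus MyHC-2A. The fold changes reached at most 2.42 log2 units between MyHC-2X and Hyb-2A/2X, and the median standard error there was 0.305. Some probes varied far more and large estimates did not pass. A_55_P2093232 differed by 2.37 ± 0.94 between these types, and A_55_P2114437 by 2.20 ± 0.92 between Hyb-2A/2X and MyHC-2A. In simulated data with the spread of these arrays, 84.0% of 50 probes changed 4-fold between MyHC-2X and MyHC-2A were called, and 32.0% of 50 changed 2-fold. These shares hold where many probes change at once, since the adjustment is stricter when few do. Simulated probes also varied independently of each other, so the shares hold for that setting only. With limma's array weights, which gave a median weight of 3.66 to the 5 Hyb-2A/2X arrays apart on the first component and 0.439 to the other 5, the counts became 0, 2300, 256 and 2732.

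The step from soleus MyHC-2X to EDL Hyb-2X/2B was wide. Hyb-2X/2B fibres had 452 probes higher and 534 lower, and 33 of these differed by 8-fold or more. Probe A_55_P2114437 was higher by 8.02 ± 1.00 log2 units (adjusted p = 5.12e-08) and reached 16.81 ± 0.21 (SD, n = 10). On 7 of 10 Hyb-2X/2B arrays it was at the highest value of the array, 16.93, which can understate its change. Among the MyHC-2X arrays it was at 15.22 and 14.69 on replicates 1 and 9 and at 5.50 to 8.25 on the other 8, so the change depends on which arrays enter, and it was 7.11 ± 1.01 without MyHC-2X replicates 6 and 8 and MyHC-2A replicates 3 and 9. Probe A_52_P362917 was higher by 4.19 ± 0.78 (adjusted p = 1.85e-04). Probe A_55_P2052330 fell by 4.78 ± 0.31 (adjusted p = 8.90e-18) and A_51_P295315 fell by 5.40 ± 0.58 (adjusted p = 6.85e-10). The fall of A_51_P295315 was not shared by all hybrid arrays. It was at 13.28 and 14.54 on Hyb-2X/2B replicates 7 and 8, from the same animal, within the MyHC-2X range of 12.55 to 16.04. On the other Hyb-2X/2B arrays that listed it the level was 6.99 to 9.59. The moderated test called 986 probes, and 1912 with the replicate number as a block in place of the animal. The types came from different muscles and different animals, so type, muscle and animal cannot be separated in this comparison.

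Within the EDL, MyHC-2B and Hyb-2X/2B fibres differed at 5 probes, all lower in MyHC-2B. Probe A_51_P193185 fell by 2.63 ± 0.45 log2 units (adjusted p = 3.52e-03) and A_51_P163031 fell by 3.73 ± 0.70 (adjusted p = 9.40e-03). The size of the latter is uncertain, since only 7 MyHC-2B arrays listed it, at a mean intensity of 43.5. This is under the highest lower limit of any array after rank normalization (66.4). Both probes were also lower in Hyb-2X/2B than in MyHC-2X, and A_51_P193185 had a mean log2 intensity of 15.38 ± 0.23 (SD, n = 10) in MyHC-2X, 11.78 ± 2.21 in Hyb-2X/2B and 9.26 ± 1.03 (n = 9) in MyHC-2B. The hybrid arrays did not lie together: A_51_P193185 was at 13.74 to 14.60 on replicates 1, 3, 7 and 8 and at 9.42 to 10.90 on the other 6. Neither the count nor the balance of higher and lower probes was stable. With missing cells at a common floor 5 probes were higher and 2 lower, with 2 of the 7 among the 5. With the first residual component as a covariate, which tends to raise counts by construction, 52 were higher and 25 lower, the 5 among them. The count was 0 with only these types in the fit or with the animal as a fixed block, 1 with fibres of an animal averaged, and 2 to 12 with a single array left out. It moved by over 1.5 times without Hyb-2X/2B replicates 2, 3, 4 or 5 (8, 2, 12 and 8 probes) and without MyHC-2B replicates 8 or 9 (8 and 9 probes).

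The ends of the range, MyHC-2B and MyHC-1, gave the most calls of the pairs compared in this fit. MyHC-2B fibres had 1111 probes higher and 800 lower, and 151 differed by 8-fold or more. Probe A_55_P2114437 was higher by 10.49 ± 0.99 log2 units (adjusted p = 2.28e-12), a change that can be understated since 9 of 10 MyHC-2B arrays had it at the highest value of the array. Probe A_51_P431785 was higher by 8.25 ± 0.49 (adjusted p = 7.15e-19) and was also high in every other fast type. The size is uncertain, since only 6 MyHC-1 arrays listed it, at a mean intensity of 44.5, under 66.4. Probe A_52_P168097 fell by 9.67 ± 1.13 (adjusted p = 2.63e-09), a size that is uncertain because only 7 MyHC-2B arrays listed it, at a mean intensity of 43.7, also under 66.4. Probe A_55_P2093232 fell by 8.56 ± 0.99 (adjusted p = 8.53e-10). The moderated test called 1911 probes, and 1254 without the 8 arrays of dimmest listed values, 3 of which are MyHC-1 and 4 MyHC-2B. Muscle and animals differ between these types as well. Of the probes called in both this contrast and MyHC-2A minus MyHC-1, 175 were higher in both, 59 lower in both and 5 opposite, against 15.2 and 3.53 in the same direction for independent lists, with r = 0.508 across probes against a simulated 0.478, a covariance of 0.187 against 0.0692, and r = 0.196 or 0.255 with MyHC-1 split.

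**Figure D4:**
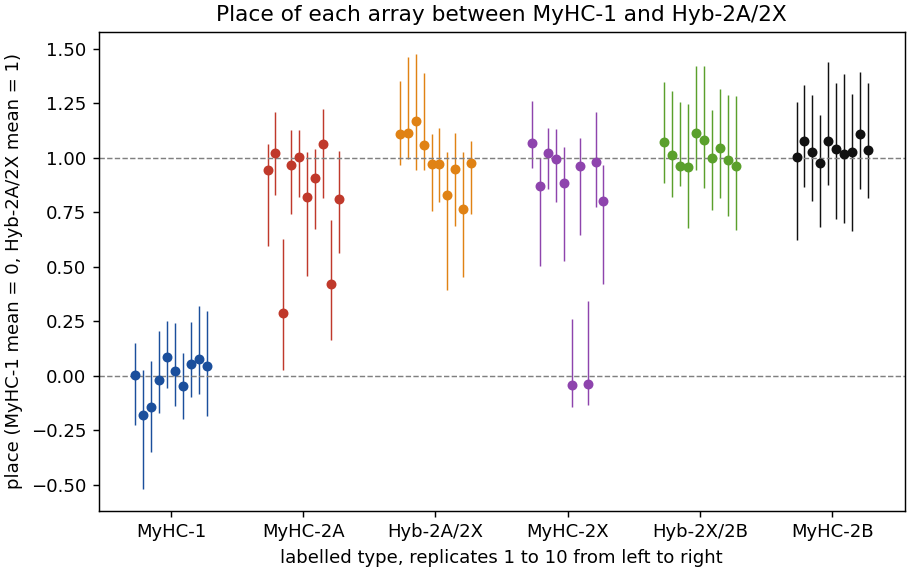
Place of each array (y axis, no unit) by labelled type (x axis), the median over 84 probes of where it lies between the MyHC-1 mean (0) and the Hyb-2A/2X mean (1), with bars for the quartiles over probes. The arrays labelled MyHC-2X replicates 6 and 8 lie at -0.04, MyHC-2A replicates 3 and 9 at 0.29 and 0.42, and the other arrays outside MyHC-1 at 0.76 or above.

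The labels were set against the arrays through probes called between MyHC-1 and Hyb-2A/2X, so the places of these 2 types are not independent of their labels. Over 84 probes that differed by 4-fold or more between Hyb-2A/2X and MyHC-1, each array was placed between the mean of MyHC-1 (0) and that of Hyb-2A/2X (1). MyHC-1 arrays lay at -0.18 to 0.09 and Hyb-2A/2X arrays at 0.76 to 1.17. The arrays labelled MyHC-2X replicates 6 and 8 lay at -0.04 and -0.04, and those labelled MyHC-2A replicates 3 and 9 at 0.29 and 0.42. The other 36 arrays outside MyHC-1 and Hyb-2A/2X lay between 0.80 and 1.11.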

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

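Tests chosen only after the result was seen were those on exchanged arrays and on mixed RNA, and the fits with a component as a covariate, with sets of arrays left out or over the always-listed probes were added after the data had been looked at. Among 102 groups of 10 arrays, 10 had an array far from the rest, and chance gives about 1 in 20. Hyb-2A/2X replicate 8 listed 31426 probes, the next 22294. MyHC-2X replicate 2 had a lowest listed intensity of 52.6, the next 30.0. Hyb-2X/2B replicate 5 had a median correlation of 0.804 to its own type, the next 0.857. The array labelled MyHC-2X replicate 6 had A_55_P2088375 at a log2 intensity of 6.73, far below the other 8 that listed it. MyHC-2B replicate 9 had A_51_P431785 at 14.81, the next 13.87. Hyb-2A/2X replicate 9 had A_55_P2090205 at 11.94, the next 9.80. MyHC-2B replicate 4 had A_55_P2114437 at 16.65 where the next was 16.93, the shared top value, and A_55_P2052330 at 5.61, the next 7.42. MyHC-2A replicate 10 had A_51_P295315 at 12.74, the next 14.51. Hyb-2A/2X replicate 5 had A_55_P2032258 at 14.54, the next 13.67. Among the control features, which the comparisons do not use, ERCC-00043_129 ranged up to an intensity of 7258 from 78.9.

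The arrays labelled MyHC-2X replicates 6 and 8 and MyHC-2A replicates 3 and 9 lay on the MyHC-1 side. An exchange with arrays labelled MyHC-1 would put a MyHC-1 array on the fast side, and the highest place there was 0.0867. These places use probes called with the same arrays, so each MyHC-1 array was also placed over probes called without it, with a highest place of 0.164. When 1 fast array was exchanged with a MyHC-1 array on purpose, all 16 such arrays lay at 0.69 or above. With 4 exchanged at once at most 9 probes were left for the place, against the 84 found, and 15 of 20 such sets left 0. A mixture of slow and fast RNA would leave fast-high probes bright, and on MyHC-2X replicates 6 and 8 the higher of the 2 places over these probes was 0.0382, which argues against it. On MyHC-2A replicates 3 and 9 the places over these probes were 0.445 and 0.573 and over slow-high probes 0.113 and 0.229, so a mixture, or a fibre that holds both programmes, stays open (0.573 decided neither way). A single wrong label, or RNA and protein that differ within a fibre, may also account for these arrays and was not tested.

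Arrays labelled MyHC-2A, Hyb-2A/2X and MyHC-2X gave no calls among themselves. Spread from the first residual component could hide them, but with it as a covariate the highest count was 0. Too little precision for 4-fold changes was tried on 10 simulated data sets with 200 probes changed in each. Of such changes between MyHC-2X and MyHC-2A 87.6% were called. The adjustment is stricter when few probes change, so this argues only against many missed 4-fold changes, and only in the simulated setting. That setting did not match the arrays in full. Its unchanged probes gave 5.11% at an unadjusted p under 0.05 in this comparison, against 1.83% of the real probes. Without the arrays labelled MyHC-2A or MyHC-2X on the MyHC-1 side the highest count was also 0. Smaller changes and a few 4-fold ones stay open, as does the weighting of arrays, with which 2300 probes were called between Hyb-2A/2X and MyHC-2A. The weights favoured the 5 Hyb-2A/2X arrays apart on the first component (median 3.66, against 0.439 for the other 5). Without the 10 arrays apart, which leaves fewer arrays, the unweighted test called 0 probes between these types.

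The step between soleus MyHC-2X and EDL Hyb-2X/2B might come from fewer listed probes on the Hyb-2X/2B arrays, but among the 8614 probes listed on all arrays 7.07% were called, against 5.72% of all tested. Muscle or animals of origin in place of MyHC type would put the hybrid near MyHC-2B. Over 964 probes called between MyHC-2B and MyHC-2X at 2-fold or more it lay a median of 0.794 of the way, and 0.770 to 0.834 without any 1 hybrid array, between the bounds of 0.65 and 0.8 set beforehand. Without the 4 arrays on the MyHC-1 side it was 0.826 (0.797 to 0.859), past the upper bound that origin would need. Type and muscle cannot be told apart here, since no type was sampled in both muscles.

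Random regroupings moved single arrays between types and kept the animal of each array in the fit, so chance among whole animals was not tested. With 100 per comparison, the real one counted, a chance arrangement of single arrays was excluded where only 1 gave as many calls. This held for the 6 types (2058 against at most 16 in the others), MyHC-2A minus MyHC-1 (312 against 19), MyHC-2X minus MyHC-1 (212 against 69), Hyb-2X/2B minus MyHC-2X (986 against 183) and MyHC-2B minus MyHC-1 (1911 against 479). For MyHC-2B minus Hyb-2X/2B 9 of 100 gave 5 or more calls, and 1 gave 349, so chance was not excluded and the arrays hold a structure other than type. For the 4 comparisons with 0 calls any regrouping gives as many (all 100), which decides nothing, and other regroupings reached 4, 0, 3 and 126.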

How the results depend on the processing

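Fixed beforehand were the scalings, filters, thresholds, weights, blocks and left-out arrays; fits without named sets of arrays, with covariates, with a common floor or without rank normalization were chosen after seeing the data. Of 308 values of named probes under these settings, 300 kept their side of the threshold and 8 lost it. These probes were picked for the largest called changes in the same arrays, which favours a high share by construction. The comparisons without calls gave no named probe. Both other scalings, the stricter filter, the common floor, no animal block and the values without rank normalization kept every count within 1.5 times. The common floor changed the balance of higher and lower probes, to 212 and 119 for MyHC-2A minus MyHC-1 (main test 236 and 76), 136 and 98 for MyHC-2X minus MyHC-1 (164 and 48) and 5 and 2 for MyHC-2B minus Hyb-2X/2B (0 and 5). Where a count moved, the cause was not tested. Counts follow in the order named.

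Array weights gave 6783 for the 6 types, 616 for MyHC-2X minus MyHC-1, 2300 for Hyb-2A/2X minus MyHC-2A, 256 for MyHC-2X minus Hyb-2A/2X, 2732 for the midpoint and 2029 for Hyb-2X/2B minus MyHC-2X, the last 2 and 2300 being above the 2019 for MyHC-2B minus MyHC-1. An adjusted p under 0.01 gave 1346 for the types, 139 and 75 for MyHC-2A and MyHC-2X minus MyHC-1, 478 for Hyb-2X/2B minus MyHC-2X and 1193 for MyHC-2B minus MyHC-1. A bound of 2-fold gave 168 (100 higher and 68 lower) and 112 for MyHC-2A and MyHC-2X minus MyHC-1. The animal as a fixed block gave 85, 44 and, for MyHC-2B minus Hyb-2X/2B, 0. Averaged fibres of an animal gave 113 for MyHC-2X minus MyHC-1 and 1 for MyHC-2B minus Hyb-2X/2B, and only the compared types in the fit gave 62 and 0. Without a filter MyHC-2B minus Hyb-2X/2B had 31. Leaving out each array gave 91 (60 higher and 31 lower) to 338 for MyHC-2X minus MyHC-1 and 2 to 12 for MyHC-2B minus Hyb-2X/2B.

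Without the 10 arrays apart on the first component MyHC-2A and MyHC-2X minus MyHC-1 had 160 and 61 (40 higher and 21 lower), and MyHC-2X minus Hyb-2A/2X had 1. Without the 8 arrays of dimmest listed values the counts were 1319 for the types, 119 (78 higher and 41 lower), 60 (29 and 31), 2 for MyHC-2B minus Hyb-2X/2B and 1254 for MyHC-2B minus MyHC-1. With the first residual component as a covariate they were 4250, 548, 493, 77 (52 higher and 25 lower) and, for Hyb-2X/2B minus MyHC-2X, 2764. That component was taken from the spread within types of these same arrays, so removing it tends to raise counts by construction. Without the 2 arrays labelled MyHC-2X on the MyHC-1 side MyHC-2X minus MyHC-1 had 483, and 488 without all 4 such arrays, of which 202 were among the 212. Those arrays were picked for resembling MyHC-1, which raises this count by construction.

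The replicate block, fitted in place of the animal block, gave 1912 for Hyb-2X/2B minus MyHC-2X and moved no other count by over 1.5 times. Leaving out the animal block alone gave 1462 there, so the move is not due to the replicate number only. The numbers were taken as names of the arrays, since only some pairs deviated together: same-numbered arrays of different types had a mean r of 0.0876, against -0.00985 for other numbers, with 4 numbers averaging over 0.1. Of 150 pairs 66 were over 0.1, and 12 of 60 arrays correlated best with their own number. Within each type the replicate numbers rise with the number of the animal. All 10 arrays apart on the first component have replicate numbers from 1 to 5. An order or batch behind the numbers was thus not excluded. The mean of the probes of a gene, and tests of gene lists, were not run because probes are not paired with genes here. Cells without a listed value limit what can be said of dim probes.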

Other observations

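The counts of probes present in a type, the grouped contrast, the places of single hybrid arrays, the test on animals behind the first component, the tests of animal pairs with arrays left out, and the choice of a single control feature all came after the data had been looked at. Some probes were seen on nearly all arrays of a type and on few of another. A probe was counted as present above a normalized intensity of 66.4, the highest lower limit of any array. The other cells were below this or unlisted, and an unlisted cell is not shown to be dim, so these numbers do not show absence. By this count 130 probes were present on at least 9 MyHC-1 arrays and at most 1 MyHC-2B array, and 70 the other way round. Random regroupings of these 20 arrays gave at most 9 in both directions together. Between soleus MyHC-2X and EDL Hyb-2X/2B the numbers were 33 and 22, against at most 4, between MyHC-1 and MyHC-2A 5 and 10, against at most 7, and between MyHC-1 and MyHC-2X 1 and 4, against at most 6. Among MyHC-2A, Hyb-2A/2X and MyHC-2X, and between Hyb-2X/2B and MyHC-2B, there were 0. The 66 probes present on all 10 MyHC-1 arrays and no MyHC-2B array were, if every unlisted cell is dim, at least 2.67-fold to at least 1724-fold higher there, with a median bound of 19.7, and the 23 probes of the opposite kind were at least 3.59-fold to at least 1756-fold higher in MyHC-2B. No probe was present in 1 type alone by this count. The arrays labelled MyHC-2X replicates 6 and 8, which lay at -0.04 beside MyHC-1, were kept. They hold down the count of probes of MyHC-1 alone and those between MyHC-1 and MyHC-2X, so these low numbers decide little.

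Taken as a group, the 3 fast soleus types differed from MyHC-1 at 684 probes, 472 higher and 212 lower. Along the probes that differed 2-fold or more between MyHC-2X and MyHC-2B, single Hyb-2X/2B arrays lay from 0.511 (replicate 8) to 1.04 (replicate 4) of the way. Replicates from the same animal were at 0.536 and 0.511 (7 and 8), 0.976 and 1.00 (9 and 10), 0.668 and 0.846 (1 and 2) and 1.04 and 0.823 (4 and 5), so some pairs were close and others not.

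A candidate explanation for the 10 arrays apart on the first component is a technical component shared with non-mouse control features. Its prediction was written first, although correlations of the controls with a closely related score had been seen by the time it was run. It predicts control features that follow the component at least as closely as mouse probes of the same brightness. The median absolute Spearman correlation of the 24 control features listed on all arrays was 0.142, below all 1000 random sets of mouse probes (median 0.358). The component was computed from mouse probes only, with the controls left out, so mouse probes follow it by construction. The lower value of the controls therefore does not decide whether they share it. The control ERCC-00043_129 still followed the first residual component (r = 0.739, rho = 0.690, each with a permutation p of 1e-05, the smallest that 100000 permutations can give, and rho also with 1e-05 for the highest of the 24 controls), and r was 0.697 without the 2 most distant arrays. The second highest absolute rho of a control was 0.569, so ERCC-00043_129 was not alone, and a component shared by some controls stays open. ERCC-00043_129 was singled out after its values were seen. Differences between animals as the whole cause would keep the arrays of an animal together, but 4 animals had arrays both inside and outside the set. A part stays open, since the 10 arrays came from only 5 animals, all 4 arrays of animal 5 were among them, and 13 of the 18 animals with 2 or more arrays lay wholly outside.

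Fibres of the same animal may resemble each other. Within types, 19 pairs from a shared animal correlated at a mean of 0.916 and 251 other pairs at 0.888, a difference of 0.0278 with a permutation p of 0.00241, and the shared pairs were higher in all 6 types. Much of this came from Hyb-2A/2X, where the difference was 0.0865, against 0.00479 to 0.0377 in the others. Without that type it was 0.0124 (p = 0.0507), and without the 10 arrays apart on the first component 0.0145 (p = 0.0169), so outside Hyb-2A/2X a shared animal is not established.

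Of 16251 probes whose identifier starts with A_30, 53 were listed on any array, against 36762 of the other 39430. Fewer calls among the tested ones had been anticipated and did not appear in the F test, where 5 of 27 were called (18.5%), against 11.9% of the others, and at matched brightness the odds ratio was 1.41 with a 95% interval of 0.499 to 3.97, so a dimmer signal of that series was not decided by so few probes. The tested ones were brighter (median log2 intensity 8.69 against 8.02), and for Hyb-2X/2B minus MyHC-2X the odds ratio was 3.43 with an interval of 1.23 to 9.58 (p = 0.0415, adjusted p = 0.166). For MyHC-2A minus MyHC-1 and MyHC-2X minus MyHC-1, 0 of 27 were called, against 1.81% and 1.23% of the others, too few to decide (p = 0.706 for the first).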
